A study of Homo sapiens with 4 samples.

How the data were processed

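CUT&RUN for GFP was carried out in HCT116 cells with a commercial kit, and the libraries were sequenced in paired-end mode at 75 bp per read, per the labels' protocols. The series held 2 WT and 2 MT libraries, grouped by their titles. Each of the 2 deposited peak lists belongs to 1 WT library, and both name MT replicate 1 as the control. Nothing in the labels says whether the replicates came from separate cultures, so spreads between them may be technical.

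The submitters' processing notes name Bowtie2 2.3.4, MACS2 2.1.2, ChIPseeker 1.28.3 and the build hg38. Peaks were called by the authors with MACS2 as narrow peaks on paired-end fragments, separately for each WT library, at a q-value cutoff of 0.05, with a smallest peak length of 200 bp, an effective genome size of 2.7e+09 and control levels over 1000 and 10000 bp, per the file headers. At most 2 fragments with the same position were kept, and the lists carry the word unfiltered in their names, per the file headers. Whether a blacklist was used is not given in the sources used here.

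The deposited pileup is the signal (fragment coverage) of the WT library at the summit. The larger of the WT and MT datasets was to be scaled to the smaller, per the file headers. All pileups were whole numbers in both lists, so the WT pileups were taken as unscaled, and the MT levels computed from them rest on that reading. The deposited fold enrichment is the ratio of that pileup to the local control level, with 1 added to both. The deposited −log10 p-value and −log10 q-value come from the Poisson test of MACS2. Positions are 1-based, per the file headers. The local MT level behind each peak was computed back from its pileup and fold. Its lowest value was 1.87 in WT replicate 1 and 2.20 in WT replicate 2, the genome background of each WT library, and 41.9% and 32.5% of peaks stood within 1% of it. At those peaks the fold was taken over that background, so a control level below it cannot raise the fold. A site with a higher true MT level that was sampled low can still fall there. The libraries had 22360060 (WT replicate 1), 27954936 (WT replicate 2) and 24097303 (MT replicate 1) fragments before duplicate filtering.

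Replicated peaks were those of WT replicate 1 that overlap a peak of WT replicate 2 by at least 1 bp, placed at the summit of WT replicate 1. Overlap was compared with 1000 shuffles of the other list within chromosome, over 1 Mb bins that hold a gene or a peak. Summits were classed, in this order, as within 1 kb of either boundary of a protein-coding gene, inside a protein-coding gene, inside an lncRNA gene, inside another gene, within 5 kb of a gene, or intergenic, and compared with 20 random positions per peak on the same chromosomes. Intervals of 95% came from 1000 bootstrap draws of 1 Mb blocks unless another kind is named. They cover the sampling of positions, not biological replicates. Peaks on the mitochondrial chromosome were left out of these comparisons.

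Genes came from a RefSeq table for GRCh38.p14 with names, classes and boundaries. No strand, exons or sequence were used here, so the planned classes of exon, intron and UTR, the gaps between convergent and divergent genes, base composition, the CTCF motif and matching on GC were not analysed here, and the planned window downstream of a gene became 5 kb on either side. For the same reason the strand of genes was taken from the side of a named divergent transcript, at most 5 kb away (563 protein-coding genes, 384 of them at least 20 kb long), or from readthrough gene names (115 pairs). This choice was made after the data were examined.

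Of 33 oxidative phosphorylation genes, 32 matched the gene table. The 25 gene lists, the rule for named genes and the settings to be varied were fixed before the data were examined. A list's share of genes with a replicated summit in the gene or within 5 kb was compared with 10000 random lists matched on gene length in 20 bins, as a permutation test of genes within length bins, with a p-value counted in both directions and Benjamini-Hochberg adjustment over the 25 lists. Random genes came from the class of most members of a list, namely protein-coding, lncRNA or all other classes together. The bins were set on protein-coding gene length, so very short genes were matched coarsely. The smallest p that the random lists can give is 0.0002. Named genes were the 12 protein-coding genes of at least 5 kb with the best worse rank of fold enrichment in both lists, the 12 with the largest share of their length under replicated peaks, in each list the 3 best members and the longest member without a replicated peak, and TOP1, TOP2A, TOP2B, CTCF, RAD21 and MYC. Not all of these are printed, and a gene that the rule names is not reported here. Correlation across autosomes used 100000 permutations, counted in both directions.

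Simulations of unenriched libraries with Poisson coverage over 2000000 windows counted windows called in both lists against a shared control. Coverage was even, or varied by region in all libraries alike. Given that coverage, windows were drawn independently, which real coverage is not, and the control level was kept at or above the genome background.

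The statistics were tested on simulated data over the real gene table. Of 30000 simulated peaks with a planted excess at gene boundaries, 26.9% were recovered there for an expected 26.9%, and randomly placed peaks gave a ratio of 1.05 for an expected 1. The expected share at boundaries came from the same classing of the same positions, so that match was fixed in advance. The ratio of starts to ends over 384 genes came out at 4.59 (3.15 to 7.05) for a true ratio of 4. Of 500 gene lists without an effect 0 were called, and 80 of 80 raised lists were called. The raised lists were those of ribosomal protein, histone, olfactory receptor and ZNF genes (69 to 477 genes), with a large planted excess. Their calls thus give no power for shorter lists or smaller excesses. In the lists without an effect each gene was hit independently, at a rate set by its length only. Clustered genes that share a peak were not imitated, so this gives no rate of false calls for clustered families.

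Alternatives were peaks above the median fold enrichment, equal numbers of peaks, the top 10000 peaks, leaving out the densest 1% of 100 kb bins, an overlap of 50% of both peaks, each WT list alone, other windows and other places for a list's summits. Alternatives chosen after the data were examined were peaks at the lowest MT level, peaks without an MT level over 10 times the lowest, random genes matched also on gene density in 5 bins, strand from names, and peaks of WT replicate 1 only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.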

Results

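GapR-GFP, a fluorescent fusion of a Caulobacter protein that binds overtwisted (positively supercoiled) DNA, was mapped by CUT&RUN in HCT116, a human colorectal carcinoma cell line. CUT&RUN cuts and releases the DNA next to an antibody-bound protein, here the GFP tag. The series held 4 libraries, 2 with the wild-type fusion (WT) and 2 labelled MT, which the series design describes as carrying a mutant GapR. The labels also gave a different genotype for MT (knockout of both type II topoisomerase genes). For all 4 libraries alike they gave palbociclib at 2 µM for 28 h, a G1 arrest, where the series design describes an asynchronous culture. These conflicts were not settled by the files, so MT is named by its label below. WT replicate 1 had 21774260 fragments after filtering, WT replicate 2 had 27443146 and MT replicate 1 had 23356540. MT replicate 2 entered neither peak list and was not analysed here. Each peak list compared 1 WT library with MT replicate 1, so a peak marks a site with more WT than MT fragments in those libraries, without a test between the groups.

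The first comparison asked whether the WT libraries placed GapR-GFP at the same sites. The list of WT replicate 1 held 81411 peaks over 64.9 Mb and that of WT replicate 2 held 42656 peaks over 29.5 Mb. Of the peaks of WT replicate 2, 84.5% (36055 peaks, 95% Wilson interval 84.2 to 84.9%) overlapped a peak of WT replicate 1, against 4.495% ± 0.104 (SD over 1000 shuffles) for shuffled positions. Of the peaks of WT replicate 1, 39.1% (31815 peaks, 38.7 to 39.4%) overlapped one of WT replicate 2, against 2.38% ± 0.0556 in shuffles. Shuffles within 1 Mb, which keep the regional density of peaks, gave 7.76% and 4.13%. These 31815 peaks are called replicated below. Some of the strongest lay in or within 5 kb of KIFC2, a kinesin motor gene (chromosome 8, 144466049 to 144474202 in hg38). Others lay as near to GRK5, a G protein-coupled receptor kinase gene (chromosome 10, 119207571 to 119459745), and to the chemokine gene CXCL16 (chromosome 17, 4733533 to 4739928).

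The fold enrichment of a peak is the authors' value within its list. A gene's value is the highest of its replicated peaks, taken in each list separately, so both values need not come from 1 site. It covers summits in the gene or within 5 kb, as do a gene's counts of summits and peaks. At KIFC2 and the neighbouring ZFTRAF1, which shared their values, it was 25.1 in WT replicate 1 and 16.6 in WT replicate 2. Replicated peaks covered 0.444% of the length of ZFTRAF1. At GRK5 it was 19.9 and 17.0, at CXCL16 19.7 and 15.2, and at the actin-binding protein gene COTL1 19.9 and 14.2. PITX3 and GBF1 shared values of 19.2 and 16.1, and DALRD3 and IMPDH2 shared values of 19.2 and 14.7. BPTF, a subunit of the NURF chromatin remodeler, had 18.9 and 13.9, and the calcium channel subunit gene CACNG2 had 19.5 and 13.5. Median fold enrichment was 4.18 (quartiles 3.42 and 5.57) in WT replicate 1 and 4.38 (3.56 and 5.63) in WT replicate 2, and median peak length was 540 and 511 bp. Across replicated peaks, which are not independent replicates, the values of both lists had a Spearman rho of 0.64. In WT replicate 1 the share of peaks found in the other list rose from 10.1% in the lowest of 5 classes of fold enrichment to 91.8% in the highest, and in WT replicate 2 from 63.9% to 99.7%.

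Both lists used the same MT library as control. In simulated libraries without enrichment called against 1 shared control, 0.0763% ± 0.241 (SD, 10 runs) of the called windows of WT replicate 2 were also called in WT replicate 1. Only 0.00734% of windows were called there for WT replicate 2, and 0% were shared when coverage varied by region. These runs decide nothing on the shared control. Few windows were called, WT and MT coverage was alike, and the control level never fell below the background. Part of the overlap may still come from the shared control, which cannot be split. When only peaks at the lowest MT level of each list were kept, 67.7% of those of WT replicate 2 overlapped one of WT replicate 1. With a required overlap of 50% of both peaks the share was 41.9%.

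The second comparison placed the peaks relative to genes. Replicated summits concentrated at the boundaries of protein-coding genes: 8740 summits (27.5%) lay within 1 kb of either end of such a gene, against 2.84% of random positions, a ratio of 9.67 (95% interval 9.24 to 10.1). The share was 14.9% in WT replicate 1 and 24.3% in WT replicate 2 (19.6% ± 6.69, SD, n = 2). Intergenic DNA over 5 kb from any gene held 14.1% of replicated summits against 32.8% of random positions, a ratio of 0.43 (0.41 to 0.45), and lncRNA genes held 8.23% against 11.9%. The interior of protein-coding genes held 40.2% of replicated summits against 43.0% of random positions. That ratio of 0.94 (0.91 to 0.96) turned to 1.31 (1.28 to 1.34) in WT replicate 1 alone, and in WT replicate 2 alone it was 1.00 (0.97 to 1.04), with no detectable difference from random positions.

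Boundary peaks also had the higher fold enrichment. Their median fold enrichment was 7.32 in WT replicate 1 and 5.63 in WT replicate 2, against 5.40 and 4.32 for intergenic replicated peaks. Of 20050 protein-coding genes, 13352 (66.6%) had a replicated summit in the gene or within 5 kb of it. Of 16841 protein-coding genes of at least 5 kb, 8130 had a replicated summit at 1 boundary and 439 (2.61%) at both, where independent placement would give 7.15%. The share at both was 8.05% in WT replicate 1 alone and 3.51% in WT replicate 2 alone, where independent placement would give 11.9% and 8.10%.

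**Figure D1:**
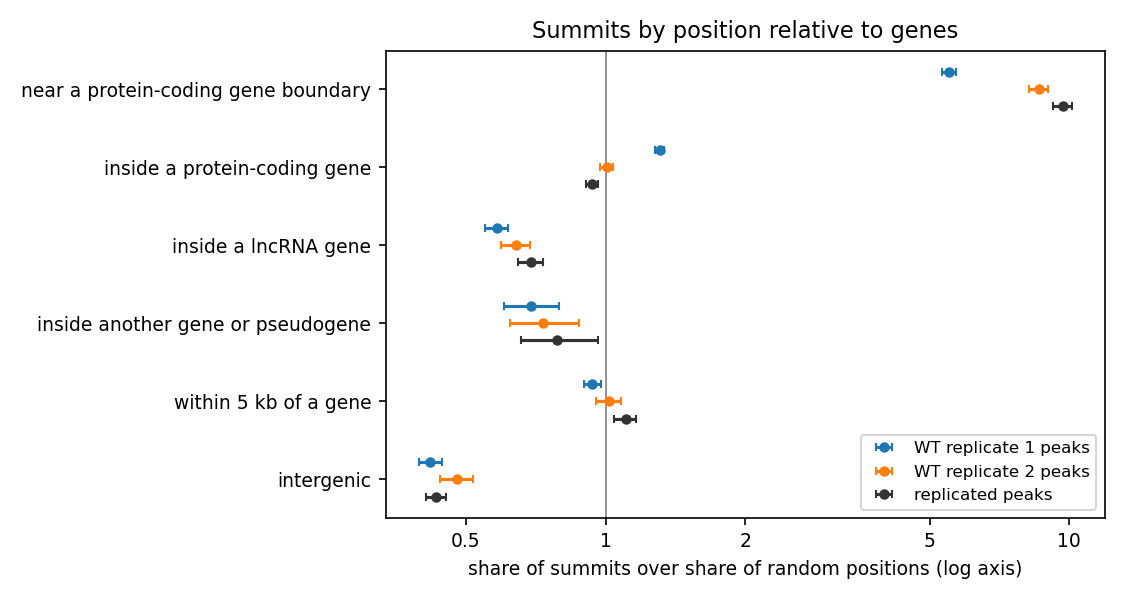
The share of peak summits in each position class is divided by that of random positions on the same chromosomes, on a log axis, for each WT list and for the replicated peaks. Points are ratios and bars are 95% block bootstrap intervals; gene boundaries stand at 5.51, 8.59 and 9.67, and intergenic DNA lies below 1 in each set.

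Genes with most of their length under replicated peaks were mostly short. RAB26, which encodes a small GTPase, was covered over 95.9% of its length (chromosome 16, 2148144 to 2154165 in hg38), and the erythropoietin receptor gene EPOR over 89.5% (chromosome 19, 11377207 to 11384314). ERRFI1, a feedback inhibitor of EGF receptor signalling, was covered over 81.1%, with a highest fold enrichment of 7.81 in WT replicate 1 and 6.44 in WT replicate 2. Genes for the EGF receptor ligands amphiregulin (AREG) and epiregulin (EREG), neighbours on chromosome 4, were covered over 72.4% and 68.4%. PDP1 (78.5%), PAGR1 (77.3%), TOB1 (72.7%), TRNP1 (72.3%), the HOXA10-HOXA9 readthrough gene (70.9%), SERTAD2 (69.2%) and METTL23 (68.4%) completed the 12 genes with the largest covered share. MYC was covered over 68.0% of its 7518 bp, with a highest fold enrichment of 13.9 in WT replicate 1 and 7.51 in WT replicate 2. Of the 24 genes chosen for the highest fold enrichment in both lists or the largest covered share, 11 had a replicated summit when only peaks at the lowest MT level were kept.

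TOP1, TOP2A, TOP2B, CTCF and RAD21, genes of topology and genome folding, each had a replicated peak, while TOP3B and SMC1A had none. As 66.6% of all protein-coding genes had one, this does not set those genes apart. TOP3B and SMC1A each had 1 summit in WT replicate 1. TOP1, encoding type I topoisomerase, held 33 summits in WT replicate 1, 8 in WT replicate 2 and 4 replicated peaks, with highest fold enrichments of 8.36 and 5.07. TOP2A had 1 replicated peak (5.87 and 7.01) and TOP2B had 3 (11.1 and 4.78). CTCF, the loop anchor protein gene, had 1 (13.6 and 8.06), and the cohesin subunit gene RAD21 had 3 (5.72 and 5.89).

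The third comparison asked on which side of genes the peaks lay, since overtwisting is expected ahead of a transcribing polymerase. Replicated peaks lay at gene starts far more than at gene ends. Around the starts of 384 protein-coding genes of at least 20 kb whose strand followed from a named divergent transcript, 0.358 replicated summits per kb per gene fell within 1 kb, against 0.0208 around their ends, a ratio of 17.2 (95% interval 11.4 to 30.6). The ratio was 6.09 in WT replicate 1 alone and 15.8 in WT replicate 2 alone. In 115 gene pairs whose strand followed from a readthrough gene name it was 20 (9.65 to 83.4).

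The 5 kb beyond gene ends held 0.0260 replicated summits per kb per gene and the 5 kb before gene starts held 0.0870, a ratio of 0.30 (95% interval 0.22 to 0.39), which was 0.556 (0.445 to 0.698) in WT replicate 1 alone and 0.280 (0.206 to 0.365) in WT replicate 2 alone. With windows of 2 kb the ratio was 0.11 and with 10 kb it was 0.46. When the 500 bp next to the gene were left out it was 0.79 (0.54 to 1.16, with 46 and 58 summits), and it was 1.04 (0.79 to 1.40) in WT replicate 1 alone and 0.595 (0.418 to 0.833) in WT replicate 2 alone, so the interval excluded 1 in WT replicate 2 and not in the other sets. Between 500 and 1000 bp from the gene, replicated summits stood at 0.161 per kb per gene before starts and 0.0208 beyond ends. Farther out the order varied. In each 500 bp step centred 3250 to 4750 bp from the gene, summits were denser beyond ends, in replicated peaks and in each WT list. At 3750 bp replicated summits stood at 0.0208 before starts and 0.0469 beyond ends. At 5250 bp they stood at 0.0260 before starts and 0.0156 beyond ends. These steps were picked from the profile and hold few summits, so no reversal is shown. The ratio of 0.30 thus rests on summits near the start. These genes have a divergent transcript by construction, so their starts are bidirectional.

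**Figure D2:**
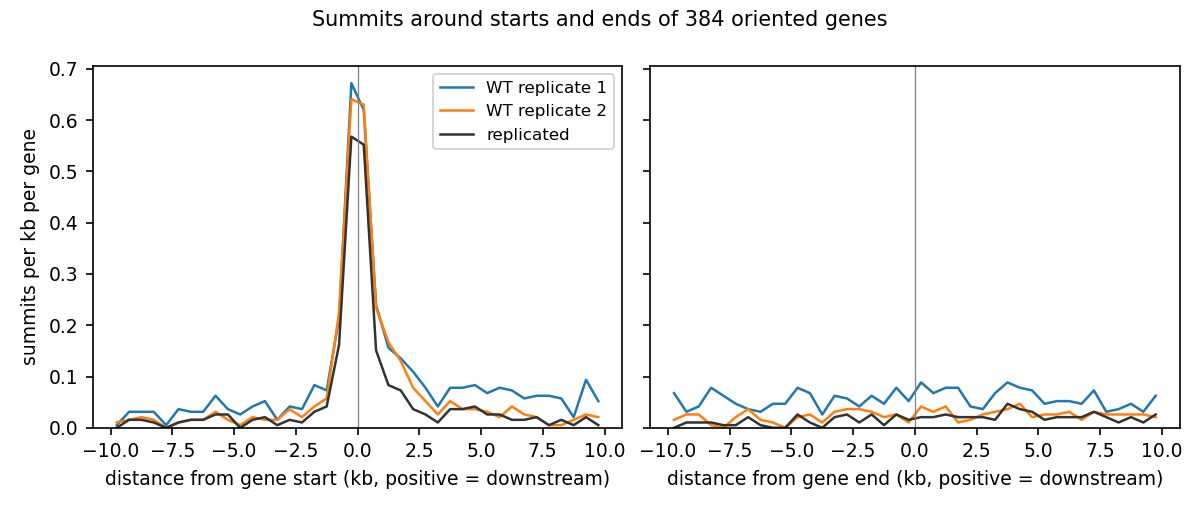
Summits per kb per gene are plotted against the distance in kb from the start (left) and the end (right) of 384 protein-coding genes oriented by a divergent transcript, with 1 line for each WT list and 1 for replicated peaks. Replicated peaks reached 0.568 just upstream of the start and stayed at 0.0208 just beyond the end.

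The fourth comparison asked which gene groups carried GapR-GFP peaks, using 25 lists fixed before the data were examined. Genes of the translation machinery, energy metabolism, cell division and stress response carried replicated peaks more often than random genes of the same length, and olfactory receptor, hepatocyte, muscle, immune cell and neuronal genes and the ZNF family less often. In all, 14 lists lay above random genes and 6 below at a Benjamini-Hochberg adjusted permutation p under 0.05, and 5 lists did neither. Each list was tested again under 13 alternatives, which were other choices of peaks, of windows or of random genes. The lists test positions in these libraries, not a difference between conditions.

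All 22 translation factor genes had a replicated summit in the gene or within 5 kb, against 65.8% of random genes (adjusted permutation p = 0.00208). EEF1A1, the elongation factor that delivers tRNA to the ribosome, had a fold enrichment of 10.5 in WT replicate 1 and 8.62 in WT replicate 2. With only peaks at the lowest MT level, the ratio of the translation factor list to random genes was 0.72, without a call on either side. Of 86 cytosolic ribosomal protein genes, 77.9% had one against 54.3% (adjusted permutation p = 0.000625, the smallest that the random lists gave), with RPL38 at 16.0 and 12.2, RPS27 at 16.4 and 11.7 and RPL13 at 15.6 and 12.5. No replicated peak overlapped RPS27 itself, so its values come from the 5 kb around it. When only summits inside the gene counted, the ratio of the ribosomal protein list to random genes was 0.87. All 18 glycolysis genes had a summit against 67.3% (adjusted permutation p = 0.00231), with the glucose transporter gene SLC2A1 at 12.2 and 10.0. Of 32 oxidative phosphorylation genes, 90.6% had one against 60.9% (adjusted permutation p = 0.00167), with COX5A at 14.1 and 10.4, and UQCRFS1 was the longest without a replicated peak. With the top 10000 peaks the ratio of this list to random genes was 0.83. Among the 13 alternatives, 6 ended the call for oxidative phosphorylation genes, 3 that for ribosomal protein genes and 2 each those for translation factor and glycolysis genes.

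All 24 immediate early genes, which respond quickly to growth signals, had a replicated summit against 54.1% of random genes (adjusted permutation p = 0.000625), with JUNB at 13.8 and 9.73, NR4A1 at 13.1 and 10.2 and EGR2 at 13.0 and 9.54. Among heat shock and chaperone genes 91.3% had one against 64.3% (adjusted permutation p = 0.00937), with HSP90AB1 at 13.6 and 11.0. Among p53 targets 95.5% had one against 67.1% (adjusted permutation p = 0.00567), with the apoptosis gene BBC3 at 12.9 and 10.3. All 25 Wnt and MYC pathway genes had one against 74.0% (adjusted permutation p = 0.00208). CCND1, encoding cyclin D1, reached 14.6 and 10.0, and TCF7L2, a transcription factor of Wnt signalling, held 24 replicated peaks. The calls for heat shock, p53 target and Wnt and MYC pathway genes were each lost under 5 of the 13 alternatives (for p53 targets, WT replicate 1 alone among them), and that for immediate early genes under 1.

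All 24 genes of G2 and M phase had a replicated summit against 69.3% (adjusted permutation p = 0.0020), with TPX2 at 14.7 and 10.0, and 92.0% of the S phase genes had one against 70.1% (adjusted permutation p = 0.0203), with the replication licensing gene CDT1 at 19.2 and 11.9. Of the 69 replication-dependent histone genes, 73.9% had one against 29.6% (adjusted permutation p = 0.000625). H2AC17, H2BC17 and H3C12 lay under a shared peak of 13.8 and 9.66, so members of this clustered family are not independent. With only peaks at the lowest MT level the ratio of the histone list to random genes was 0.65, without a call on either side. The cohesin, condensin and CTCF list stood at 95.8% against 77.3% (adjusted permutation p = 0.0410), a call that ended when random genes were also matched on gene density, in each WT list alone and under 9 of the 13 alternatives in all. The S phase call ended under 7, the G2 and M phase call under 4 and the histone call under 3.

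Among noncoding genes, all 16 housekeeping short noncoding RNA genes had a replicated summit against 15.6% (adjusted permutation p = 0.000625). Their random genes were neither protein-coding nor lncRNA genes and included 15580 pseudogenes, of which 2.74% had a replicated summit within 1 kb. Length was matched only coarsely for such short genes, so 15.6% is not the share of comparable RNA genes. They include RMRP (10.8 and 9.08), RN7SL1 (11.5 and 7.90) and RPPH1 (10.8 and 7.62), the RNA genes of RNase MRP, the signal recognition particle and RNase P. Some have near-identical copies, so their read placement is uncertain. Of 16 abundant lncRNA genes, 75% had one against 33.0% (adjusted permutation p = 0.00393), with MALAT1 at 19.5 and 16.9, GAS5 at 19.6 and 8.17 and CYTOR at 15.3 and 8.21. The short noncoding RNA call ended under 3 of the 13 alternatives, at ratios to random genes of 17.1 inside gene spans, 5.10 at the lowest MT level and 1.16 with peaks of WT replicate 1 only, and the lncRNA call under 1, at 3.12 with the lowest MT level, against 6.42 and 2.27 for replicated peaks. In WT replicate 1 alone the short noncoding RNA ratio was 3.87.

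Of the lists typical of other tissues, 5 lay below random genes, and the fibroblast and mesenchymal list did not pass, at a ratio of 0.70. It passed as below random genes under 3 of the 13 alternatives, namely peaks above the median fold enrichment (0.35), the top 10000 peaks (0.16) and summits at gene boundaries (0.29). Among 390 olfactory receptor genes 5.64% had a replicated summit against 43.7% (adjusted permutation p = 0.000625), a ratio of 0.129 that was 0.217 in WT replicate 1 alone, with a share of 11.5%. Hepatocyte genes had 16.7% against 61.3% (adjusted permutation p = 0.000625), muscle genes 29.6% against 64.6% (adjusted permutation p = 0.000625), immune cell genes 37.5% against 63.3% (adjusted permutation p = 0.0203) and neuronal genes 48.0% against 73.7% (adjusted permutation p = 0.0138). RYR2, GABRB2 and NCAM1, each the longest of its list without one, had no replicated peak. The ZNF family, 477 genes of which many lie clustered on chromosome 19, had 57.2% against 69.4% (adjusted permutation p = 0.000625). In the list of WT replicate 1 alone the calls for muscle, immune cell and neuronal genes ended, with shares of 66.7%, 70.8% and 72.0% and ratios to random genes of 0.88, 0.95 and 0.84, while that for hepatocyte genes held at 45.8% and a ratio of 0.63. Over the 13 alternatives, the neuronal call ended under 8, WT replicate 2 alone among them, the muscle and immune cell calls under 4 each and the hepatocyte call under 1.

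The remaining 5 lists fell on neither side, namely colorectal epithelium (74.3% against 65.5%, adjusted permutation p = 0.379), fibroblast and mesenchymal genes (50% against 71.1%, adjusted permutation p = 0.0795), protocadherin clusters (60.4% against 72.2%, adjusted permutation p = 0.0750), topoisomerases (81.8% against 75.04%, adjusted permutation p = 0.906) and very long or fragile-site genes (69.0% against 72.6%, adjusted permutation p = 0.836). Among the last, FHIT and CTNNA3 each held 5 replicated peaks and RBFOX1, 2473620 bp long, held none. Colorectal epithelium passed as above random genes under 1 of the 13 alternatives, peaks above the median fold enrichment (ratio of 1.40). Very long or fragile-site genes passed as below under 2, among them peaks of WT replicate 1 only (58.6% against 84.0%). The protocadherin clusters passed the test as below random genes under 6 of the 13 alternatives, among them each WT list alone (ratios of 0.84 and 0.82) and random genes matched on gene density (0.72, adjusted permutation p = 0.000455). Protocadherin genes overlap and share peaks (the same 4 at PCDHA1, PCDHA10 and PCDHA11), so members of this list are not independent either. The number of lists above random genes depended on the peaks used. It was 5 when only summits inside the gene span counted, 6 with the top 10000 peaks, 7 with a required overlap of 50% and 1 with peaks at the lowest MT level. At that level 32.7% of protein-coding genes had a summit, and calls also ended at ratios near or above those of all replicated peaks, with 1.88 for immediate early genes, 1.69 for p53 targets, 1.56 for heat shock genes, 1.47 for Wnt and MYC pathway genes and 1.40 for G2 and M phase genes.

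**Figure D3:**
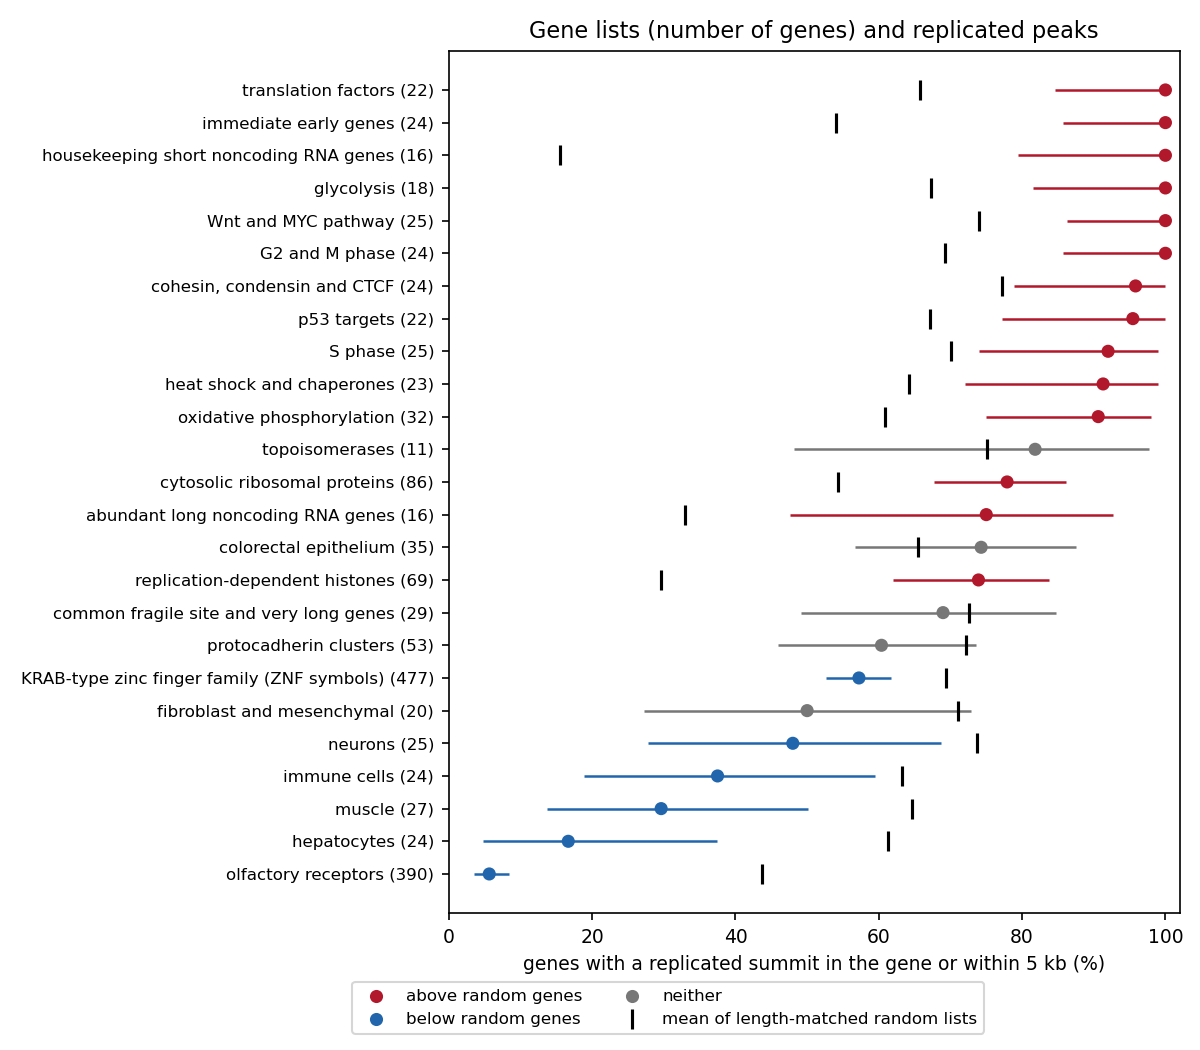
The percentage of genes with a replicated summit in the gene or within 5 kb is shown for each of 25 gene lists, as points with exact 95% binomial intervals, beside the mean of 10000 random lists matched on gene length. The 14 lists above random genes range from 73.9 to 100% and the 6 below from 5.64 to 57.2%.

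A last comparison set peak density by chromosome. Chromosomes 19 and 17, the most gene-rich, held 24.9 and 24.6 replicated peaks per Mb, and chromosome 13 held 6, with a median over the 22 autosomes of 10.7. Density followed the number of protein-coding genes per Mb across the autosomes (Pearson r = 0.91, Spearman rho = 0.88, permutation p = 1e-05 for each, the smallest that 100000 permutations give), and r was 0.88 without the 2 chromosomes farthest from the median gene density. Both tests form 1 family of the same relation. Per protein-coding gene, the autosomes ranged from 1.01 replicated peaks on chromosome 19 to 2.24 on chromosome 10. The X chromosome held 1.95 replicated peaks per Mb, or 0.353 per protein-coding gene against 1.65 on the autosomes. In WT replicate 1 alone it held 1.27 per protein-coding gene against 4.20, and in WT replicate 2 0.421 against 2.21. The copy number of chromosomes in these cells, on which the number of called peaks depends, was not used here.

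**Figure D4:**
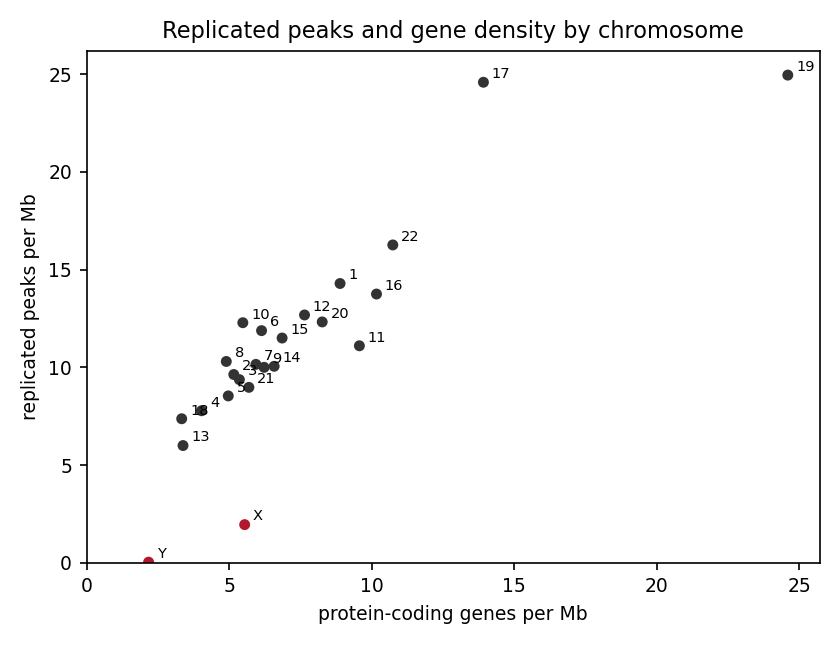
Replicated peaks per Mb are plotted against protein-coding genes per Mb, with 1 labelled point for each chromosome and the sex chromosomes in red. Chromosome 19 lies highest at 24.9 peaks per Mb and X lies at 1.95, below each autosome.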

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

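The tests of library depth and of equal fold enrichment were chosen after their results were seen. The match on gene density was added after the data were examined, with its bounds set before its own result was seen, as were those of the test of MT levels. In WT replicate 1, 7 peaks lay on the mitochondrial chromosome, with fold enrichments over MT replicate 1 of up to 1.28, and WT replicate 2 had 0. These peaks lay outside the comparisons above.

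Of the 49596 peaks found in WT replicate 1 only, which the comparisons above leave aside, 63.2% had their summit over 2 kb inside a protein-coding gene, against 41.2% of random positions and 37.1% of replicated peaks. WT replicate 1 had 1.91 times as many peaks as WT replicate 2, and greater depth is argued against, because it had 0.793 times the fragments. With equal numbers of peaks the share in gene interiors was 41.7% in WT replicate 1 and 39.4% in WT replicate 2, a difference of 2.33 percentage points (95% interval 1.63 to 3.02). That lay within the bound set beforehand for a longer list that only reaches weaker peaks of the same kind. At equal fold enrichment, with classes weighted as in WT replicate 2, the share was 52.7% and 39.4%, a difference of 13.4 points (12.7 to 14.0). This later test, chosen after its result was seen, goes against such a list. However, fold enrichment may not have 1 scale in both libraries (medians of 5.92 in WT replicate 1 and 4.69 in WT replicate 2 across replicated peaks). A longer list of this kind therefore cannot be told apart from a difference between the libraries, why the shallower library gave the longer list stays open, and no biological explanation was tested.

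Replicated peaks stood at gene boundaries, where chromatin is often open, and the MT library could share cutting of open chromatin at a lower yield. Among boundary peaks the median MT level in the highest of 5 classes of WT pileup was 1.27 times that in the lowest (95% interval 1.27 to 1.33). This ratio decides nothing, because 68.4% of the peaks in the lowest class stood at the lowest MT level, the background below which MACS2 gives no value. The explanation cannot be told apart from binding of the WT protein with these lists, which give MT levels only under WT peaks. A difference between the WT and MT protein stays open as well, and was untested.

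Lists of active cell functions lay above random genes and 5 lists of other tissues below, and gene-dense regions could produce this. With random genes matched on gene density as well as length, 19 of the 20 lists that stood apart did so in the same direction, which argues against gene density as the whole cause. Open chromatin and transcription, for which no values were used here, stay open.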

How the results depend on the processing

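The settings on MT level, gene density, strand source and peaks of WT replicate 1 only were chosen after the data were examined. No paired analysis was possible because only MT replicate 1 enters the lists, as the control of both, and MT replicate 2 is in neither. The alternatives that need sequence, repeats, strand for each gene or exons were not run. Depth limits the lists to sites with enough WT fragments over background, so a gene without a peak is not shown to lack GapR-GFP.

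The excess at gene boundaries, the deficit in intergenic DNA and the excess of gene starts over ends kept their direction and excluded 1 under each alternative on replicated peaks or a whole WT list, with ranges of 5.51 to 14.7, 0.29 to 0.53 and 6.09 to 23.4. With peaks of WT replicate 1 only, the ratios were 2.64 at boundaries, 0.41 in intergenic DNA, 1.55 inside protein-coding genes, 1.54 for starts over ends (1.00 to 2.35, so 1 was not excluded) and 1.14 for ends over starts. The overlap of WT replicate 2 peaks stayed above the shuffles throughout, from 41.9 to 91.1%. The ratio inside protein-coding genes turned to 1.31 in WT replicate 1 alone and was 1.00 (0.97 to 1.04) in WT replicate 2 alone. The ratio of gene ends to starts lost its difference with 500 bp left out (0.79), also in WT replicate 1 alone (1.04) but not in WT replicate 2 alone (0.595).

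The count of lists above random genes was 6 with the top 10000 peaks, 1 at the lowest MT level, 7 with 50% overlap, 5 inside gene spans and 5 with peaks of WT replicate 1 only. The rank correlation of fold enrichment moved to 0.54 (above median fold), 0.62 (equal numbers), 0.47 (top 10000 peaks), 0.65 (lowest MT level) and 0.69 (50% overlap). Highest over lowest autosomal density was 4.16, moved to 6.23 (top 10000 peaks) and 7.47 (lowest MT level), and spanned 2.90 to 4.50 in single lists. Where the fewer peaks of a setting did not account for a change, the cause was not tested.

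Some lists changed side of random genes, as ratios of observed to random share. A change of side is read from the ratio alone, whether or not the list was called. They were protocadherins (1.01 above median fold, 1.02 inside gene spans), oxidative phosphorylation (0.83) and topoisomerases (0.86) with the top 10000 peaks, topoisomerases without the densest bins (0.98), and at the lowest MT level histones (0.65), translation factors (0.72), cohesin (0.99) and topoisomerases (0.75). Ribosomal proteins turned inside gene spans (0.87), colorectal epithelium at boundaries (0.71) and very long genes with matched density (1.00). With peaks of WT replicate 1 only, colorectal epithelium (0.84), immune cell (1.02) and muscle genes (1.19) turned. Of 325 list alternatives, 232 kept both direction and call, 66 lost the call, 12 gained one and 15 turned.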

Other observations

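The tests beyond gene ends in this part were chosen after their results were seen. Most tRNA genes had a replicated summit nearby. Of 443 tRNA genes, 63.9% (exact binomial 95% interval 59.2 to 68.4%, which takes genes as independent) had a replicated summit within 1 kb, against 2.95% of random positions. In single lists the share was 69.1% for WT replicate 1 and 70.2% for WT replicate 2, and 12.9% of tRNA genes had one when only peaks at the lowest MT level were kept, against 0.790% of random positions. For 154 snRNA genes the share was 37.0% against 3.15%, and for 1913 miRNA genes 9.67% against 2.39%. At the lowest MT level the excess of snRNA genes ended, with 2 of 154 against 1.27% of random positions, and miRNA genes had 4.03% against 0.685%. In WT replicate 1 alone the miRNA share was 15.8% against 5.49%. Of 15580 pseudogenes, 2.74% had one against 3.44%, with 6.51% against 7.59% in WT replicate 1 alone and 3.23% against 4.20% in WT replicate 2 alone. Clustered tRNA and snRNA genes can share a peak, and near-identical copies share reads.

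Among 8840 protein-coding genes over 30 kb, the tenth with most interior summits per length in WT replicate 1 held 34.8% of the interior summits of WT replicate 2, on 6.57% of the length. Both lists share a control, and genes are not independent replicates. The following genes were chosen after their values were seen. SMURF2, encoding a ubiquitin ligase, held 51 interior summits in WT replicate 1 and 37 in WT replicate 2, EZR, encoding ezrin, held 28 and 19, and CLTC, encoding clathrin heavy chain, held 36 and 14. RAD23B held 28 and 7, and PPP1CB held 22 and 4 with 0 replicated.

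At MALAT1 the highest peak of WT replicate 1 (chromosome 11, 65504208 to 65511343 in hg38) had its summit 1418 bp past the right boundary of the gene, and that of WT replicate 2 lay 1395 bp past it. At the neighbouring NEAT1, which is 22743 bp long, the highest summits lay at -26552 and -23609 bp from the right boundary, beyond the left one in both lists. At the ribosomal RNA gene copy RNA45SN2 the highest peak reached 7.22 in WT replicate 1 and 5.96 in WT replicate 2, with the summit 675 bp past the right boundary in both. At other copies the highest summits of the lists lay apart, at -1399 and 1162 bp from the right boundary of RNA45SN1 and at -14282 and 473 bp from that of RNA45SN3. Reads at these copies are shared between copies, so the copy is uncertain. Of the X chromosome peaks of WT replicate 1, 87.0% stood at the lowest MT level, against 41.3% of autosomal peaks.

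A hypothesis was that GapR-GFP gathers just beyond gene ends, where overtwisted DNA might collect ahead of the polymerase. In the 384 genes oriented by a divergent transcript, the 5 kb beyond the end held 1.56 times (95% interval 1.02 to 2.41) as many replicated summits as the last 5 kb of the gene. The ratio was 1.22 (0.965 to 1.54) in WT replicate 1 alone and 1.21 (0.843 to 1.84) in WT replicate 2 alone, and 1.25 (0.526 to 3.00) for replicated peaks in the genes oriented by readthrough names. Since each single list includes 1, an excess beyond gene ends is not shown by these lists, and the number of summits limits the test.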
